A study of Mus musculus with 12 samples.

How the data were processed

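The deposited values are log2 signals of 45141 probe sets on 12 arrays, made with RMA per the submitters' processing notes; the version of the software is not given in the sources used here. RMA as usually run brings the arrays to a shared distribution of probe signals, which can hide a shift of all genes at once, and it compresses changes of very bright and very dim probe sets. The array medians lay between 3.94 and 4.00, and no further scaling was applied. Total RNA was extracted from liver with Trizol and labelled with biotin per the labels.

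Control probe sets, 104 in number, were left out. A single gene was given for 28898 probe sets, several genes for 551 and none for 15588; probe sets with several genes were not used. Symbols were brought up to date through their gene identifiers, 28689 of which were found, and 0 symbols changed. Where a gene had several probe sets, the one with the highest mean over all arrays stood for it. Of 17097 genes, the 40% with the lowest mean (6839 genes) were left out as dim, which left 10258 genes with a mean of at least 4.08.

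Differences were fitted in R 4.3.3 with limma 3.58.1, as means of the 4 groups over all 12 arrays (8 residual degrees of freedom) with a variance trend. A gene passed at an adjusted p of 0.05 after the Benjamini-Hochberg correction over the genes tested in a comparison, and no correction was made across the 6 comparisons. The comparisons were knockout minus wild type on each diet and averaged over both diets, high-fat minus low-fat diet in each genotype, and the difference between these diet effects. The labels do not say that extracts of the same number belong together, so the numbers were not used as a block. The smallest exact permutation p for 3 against 3 arrays is 0.1, so no permutation test of single values was made. Values after ± are SD over the 3 arrays of a group, and SE are limma's.

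Gene lists written before the data were examined, 46 in number, were tested with camera at its preset correlation of 0.01 between genes, and the 38 lists with at least 5 tested members entered the correction. Camera with a correlation estimated from the data and fry were the alternatives. Members of each list were also adjusted over the list alone. Random splits of the arrays, up to 100 with a fixed seed, gave the counts to be had by chance.

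The named genes follow a rule written before the data were examined: Pml; the 10 largest rises and 10 largest falls among the genes that passed; the 5 with the smallest p where none passed; up to 4 of the members past the threshold of each list, by size; and 22 genes of lipid metabolism always considered. Any gene named where it falls outside this rule, such as members of lists in which none passed, was chosen after its values were seen. Of these genes, Ppargc1a, Cyp4a14, Cidec and Srebf1 had no probe set with a single gene, some others are not reported here, and Pparg, Pdk4, Cidea and Cyp2b10 lay under the filter.

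A run with known changes put into the comparison of genotypes on the low-fat diet recovered 56.7% of the genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold, 200 genes in all, with 6 false calls among 170. A list shifted by 0.5 on the log2 scale passed camera (adjusted p = 3.9e-24, and adjusted p = 0.000112 with an estimated correlation), and 0 other lists did. In this run the noise of each gene was drawn independently, so it does not show how the list tests behave where genes move together. Alternatives planned before the data were examined were quantile normalization, median centring, no filter and a 60% filter on dim genes, the mean of a gene's probe sets, robust variance, no variance trend, a fit of the 2 groups alone, the replicate number as a block, array weights, an adjusted p of 0.10, and leaving out each array. A fit without the 2 arrays with the lowest macrophage markers and the PML list without Pml were chosen after seeing the data.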

Results

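Gene expression was measured in livers of male mice that carried or lacked Pml, the gene of the protein that organises the nuclear bodies named after it. The mice had eaten a low-fat diet, with 10% of calories from fat, or a high-fat diet, with 60%, for 20 weeks. They were fasted for 8 h before the livers were taken. The title of the series names PPAR signalling and the burning of fatty acids as its subject. The livers fall into 4 groups by genotype and diet, with 3 livers taken from the 8 mice of each group. Each of the 12 liver extracts was hybridised to its own array. The labels number the extracts 1 to 3 within a group and do not say that extracts of the same number belong together, nor outright that each came from its own mouse. The p-values therefore measure the spread between these extracts. The number of arrays, 3 a group, limits the precision.

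The 12 arrays were alike in their overall profiles, with Pearson's r between arrays from 0.986 to 0.995 across all 45141 probe sets, which are not independent replicates. The first principal component held 24.1% of the variance and separated the diets. The 6 low-fat arrays had scores from -15.8 to -1.73 and the 6 high-fat arrays from 3.99 to 17.5. The second component held 16.6% and set knockout low-fat replicate 2 apart at -22.0. In this array the macrophage and Kupffer cell markers averaged 5.31 on the log2 scale. In knockout high-fat replicate 3 they averaged 5.85, against 6.26 to 7.06 in the other 10 arrays. Liver endothelial markers were also low in knockout low-fat replicate 2 (-0.56 relative to the mean of all arrays) and in knockout high-fat replicates 2 and 3 (-0.59 and -0.63), against -0.003 to 0.52 elsewhere. The 3' minus 5' signal of actin, a sign of RNA quality, was 1.51 ± 0.304 (SD, n = 3) in wild-type low-fat, 1.58 ± 0.065 in wild-type high-fat, 1.52 ± 0.0356 in knockout low-fat and 1.43 ± 0.0127 in knockout high-fat livers.

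Pml was low in every knockout liver. The brighter of its 2 probe sets had a log2 signal of 5.13 ± 0.246 (SD, n = 3) in wild-type livers on the low-fat diet and 5.23 ± 0.229 on the high-fat diet. The values were 5.40, 4.92 and 5.07 in the single low-fat livers and 4.97, 5.35 and 5.38 in the high-fat livers. In knockout livers it was 3.63 ± 0.0605 on the low-fat diet and 3.43 ± 0.388 on the high-fat diet. The single livers had 3.70, 3.59 and 3.59 on the low-fat diet and 3.42, 3.04 and 3.82 on the high-fat diet. The second probe set was dim in all groups, at 3.29 and 3.12 in wild-type and 2.90 and 2.90 in knockout livers. The knockout signal lay below 4.08, the lowest mean among the genes tested. Changes of dim probe sets tend to be compressed, so folds of Pml may be lower bounds. Averaged over the diets, Pml was 3.15-fold lower in knockout livers (log2 change -1.66, SE 0.133, limma adjusted p = 0.000225 after Benjamini-Hochberg). The labels do not say whether these probe sets lie in the part of the gene that was removed, so the signal may not show how far the gene was lost. It did set every knockout liver (3.04 to 3.82) below every wild-type liver (4.92 to 5.40), as the genotype labels have it.

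**Figure D1:**
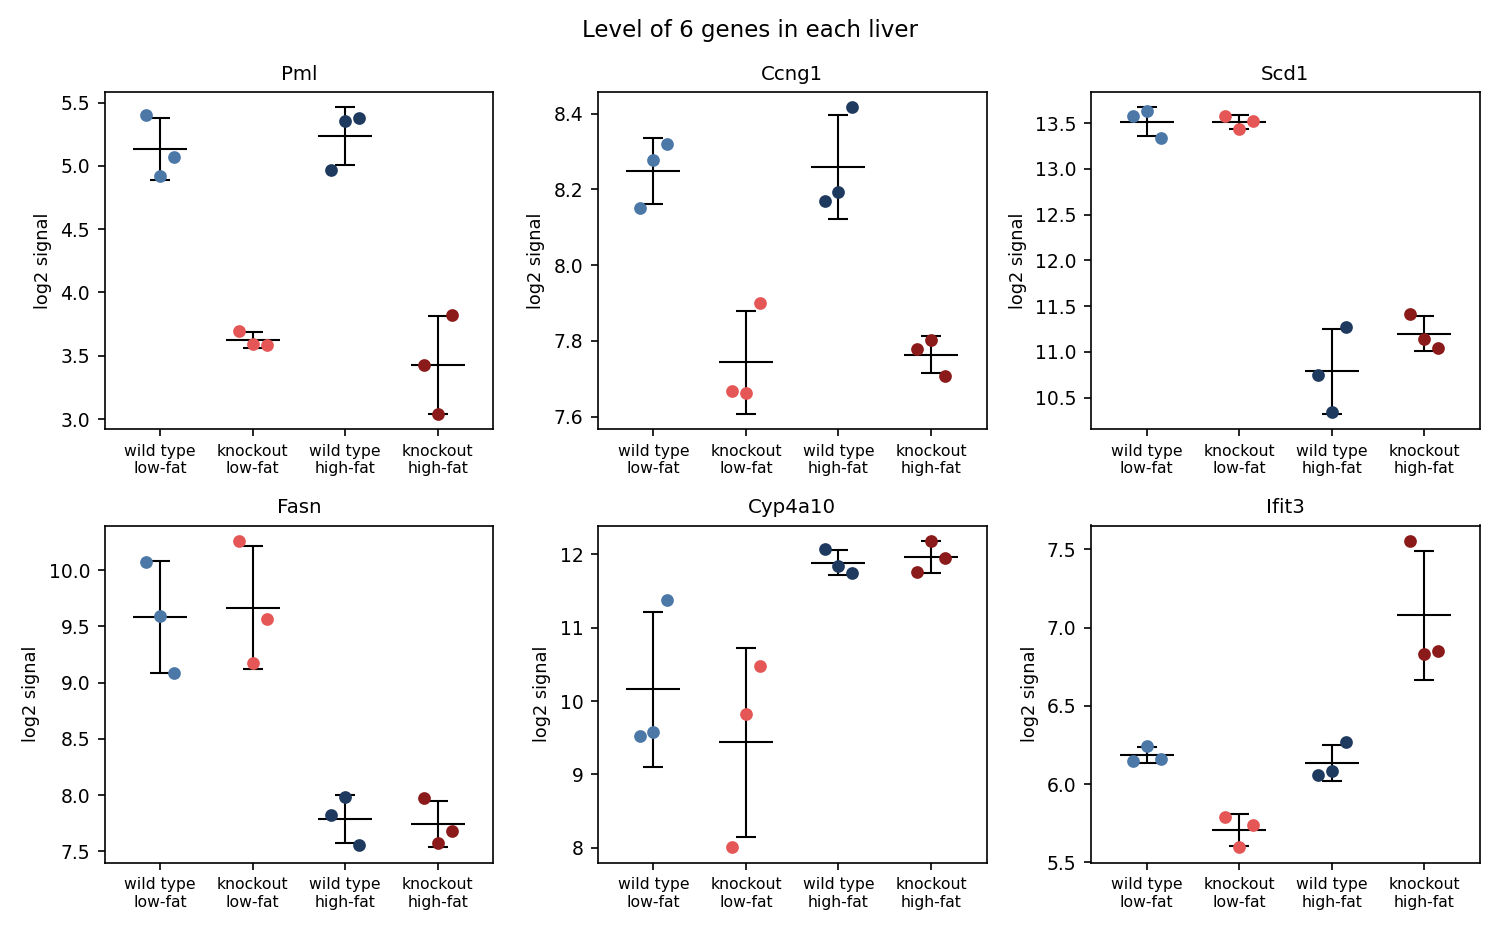
Log2 signal of Pml, Ccng1, Scd1, Fasn, Cyp4a10 and Ifit3 (vertical axes, not starting at 0) in the 4 groups (horizontal axis); each point is 1 liver, the long bar is the group mean and the whiskers are ± 1 SD (n = 3). Pml was at or below 3.82 in the 6 knockout livers and at or above 4.92 in the 6 wild-type livers, and Scd1 was at or above 13.3 on the low-fat diet and at or below 11.4 on the high-fat diet.

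On the low-fat diet, the comparison of knockout with wild-type livers asks what the loss of Pml did without a fat load. Pml itself was 2.84-fold lower (log2 change -1.51, SE 0.188, limma adjusted p = 0.0303) and was the 1 gene of 10258 that passed. An unadjusted p under 0.05 was found for 895 genes, where 512.9 would be expected by chance. Genes of PPAR-alpha, the nuclear receptor that switches on fatty acid burning in liver, had lower values in knockout livers. Of the tested targets 11 of 12 were lower, with a mean log2 change of -0.36. Ppara itself had a log2 change of -0.47 (SE 0.0975, adjusted p = 0.222). Acot1, an acyl-CoA thioesterase, had -1.09, Cyp4a10, a fatty acid hydroxylase, -0.72 (SE 0.551) and Fgf21, a fasting hormone, -0.60 (SE 0.456). None of the 12 passed among all genes tested, and 2 were lower when adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 0.0122), but not otherwise (adjusted p = 0.991 with an estimated correlation).

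Peroxisomal fatty acid oxidation was lower in 12 of 15 members (mean log2 change -0.18, median -0.05, camera adjusted p = 0.0406, and adjusted p = 0.991 with an estimated correlation), with Acot3 at -1.47 and Decr2 at -0.40. None of these 15 passed among all genes, and 1 was lower when adjusted over the list alone. Targets of p53, the stress-activated tumour suppressor, were lower in 15 of 16 members (mean log2 change -0.26, camera adjusted p = 0.00199, and adjusted p = 0.606 with an estimated correlation). Among them the cell cycle inhibitor Cdkn1a had a log2 change of -0.95 and Ccng1, a cyclin induced by p53, -0.51. None of the 16 passed among all genes, and 1 was lower when adjusted over the list alone. Mitochondrial fatty acid oxidation, with 13 of 18 members lower and a mean log2 change of -0.10, did not pass (camera adjusted p = 0.453). Cpt1a, its entry enzyme, had -0.23 (SE 0.0995). The lipogenic enzymes Scd1 and Fasn had log2 changes of -0.01 (SE 0.178) and 0.09 (SE 0.268).

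These low-fat results rest on few arrays. Pml missed the threshold without wild-type low-fat replicate 1, 2 or 3, wild-type high-fat replicate 2 or 3, knockout low-fat replicate 2 or 3, or knockout high-fat replicate 1 (adjusted p up to 0.198, log2 change from -1.61 to -1.37), and 4 genes passed without knockout low-fat replicate 1. The PPAR-alpha list missed it without wild-type low-fat replicate 3 (mean -0.19), knockout low-fat replicate 1 (-0.17) or knockout low-fat replicate 3 (-0.42). The peroxisomal list missed it without those 3 or wild-type low-fat replicate 2 (adjusted p from 0.109 to 0.353), and the p53 list without wild-type low-fat replicate 3 (-0.22).

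On the high-fat diet, knockout livers had higher values of interferon-stimulated and other inflammatory genes than wild-type livers. Pml was 3.49-fold lower (log2 change -1.80, SE 0.188, limma adjusted p = 0.00433) and was again the 1 gene of 10258 that passed. There were 457 genes at an unadjusted p under 0.05 against 512.9 expected. Interferon-stimulated genes were higher in 19 of 21 members, with a mean log2 change of 0.49. Ifit1 had 1.25, Gbp3 1.17 and Ifit3, which like Ifit1 restrains viral RNA, 0.94 (SE 0.167, adjusted p = 0.311). None of the 21 passed among all genes tested, and 11 were higher when adjusted over the list alone. The list passed camera (adjusted p = 5.98e-15), but adjusted p = 0.147 with an estimated correlation.

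Inflammatory cytokines and chemokines were higher in 8 of 9 members (mean 0.52, median 0.28, camera adjusted p = 0.000142, and adjusted p = 0.221 with an estimated correlation), led by the T cell attractant Cxcl9 at 2.36 (SE 0.49, adjusted p = 0.643). The acute phase response, the set of plasma proteins the liver releases in inflammation, was higher in 18 of 24 members, with a mean of 0.25 and a median of 0.07 (camera adjusted p = 0.000142, and adjusted p = 0.147 with an estimated correlation). Its largest values were those of Lcn2, at 1.78, and Saa3, at 1.49. Adjusted over the list alone, 1 of the 9 cytokines and chemokines and 4 of the 24 acute phase genes were higher, against 0 of either among all genes. Neutrophil markers, which share Lcn2 with that list, had a mean of 0.30 and a median of 0.08 (camera adjusted p = 0.0287, and adjusted p = 0.221 with an estimated correlation), with 1 of 8 higher when adjusted over the list alone. Genes of MHC class II and antigen presentation had a mean of 0.30 (camera adjusted p = 0.00584, and adjusted p = 0.598 with an estimated correlation), with 0 members past the threshold either way.

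Drug-metabolising targets of the constitutive androstane and pregnane X receptors were higher in 12 of 14 members (mean 0.17, camera adjusted p = 0.000492, and adjusted p = 0.23 with an estimated correlation), with Cyp3a11 at 0.84. Cyp2b10, a member left out of the test as dim, went the other way, at -1.29 (SE 0.372). NRF2 antioxidant genes (mean 0.17, camera adjusted p = 0.034, and adjusted p = 0.598 with an estimated correlation) and pericentral hepatocyte markers (mean 0.16, median 0.10, camera adjusted p = 0.0287, and adjusted p = 0.436 with an estimated correlation) were the other lists with higher values. Liver endothelial markers were lower in 12 of 12 members (mean -0.50, camera adjusted p = 7.9e-07, and adjusted p = 0.435 with an estimated correlation, which was 0.879 for this list). PML nuclear body components were also lower (mean -0.28, median -0.12, camera adjusted p = 0.000311, and adjusted p = 0.209 with an estimated correlation), with a mean of -0.13 without Pml itself. So were male-biased liver genes (mean -0.20, median -0.12, camera adjusted p = 0.000608, and adjusted p = 0.598 with an estimated correlation) and the unfolded protein response (mean -0.20, median -0.08, camera adjusted p = 0.0241, and adjusted p = 0.598 with an estimated correlation). Insulin signalling (mean -0.18, median -0.10, camera adjusted p = 0.0252, and adjusted p = 0.435 with an estimated correlation), p53 targets (mean -0.12, camera adjusted p = 0.0304, and adjusted p = 0.435 with an estimated correlation) and exocrine pancreas markers (mean -0.18, camera adjusted p = 0.0287, and adjusted p = 0.271 with an estimated correlation) were lower too. Of these 10 lists the PML nuclear body list had 1 member, Pml, past the threshold among all genes and 2 when adjusted over the list alone. The p53 list had 0 and 2, and the other lists had 0 and 0.

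As lists, the fatty acid genes differed little between genotypes on this diet. The PPAR-alpha list had a mean log2 change of -0.07 and mitochondrial fatty acid oxidation 0.01, neither past the threshold (camera adjusted p = 0.314 and 0.52). Single values were -0.11 (SE 0.0975) for Ppara, 0.07 (SE 0.551) for Cyp4a10, 0.11 (SE 0.0549) for Acadm and 0.41 (SE 0.178) for Scd1. Fgf21, which was also lower on the low-fat diet, had -0.471 and Angptl4 had -0.395, neither past the threshold. The interferon, cytokine, acute phase, endothelial, receptor and PML list calls held without each array in turn, but the receptor mean was 0.11 without wild-type high-fat replicate 2 and the endothelial mean -0.78 without knockout high-fat replicate 1. The size of 3 other lists also moved by over 1.5 times with the call kept. Insulin signalling was -0.28 without knockout high-fat replicate 1, MHC class II 0.55 without knockout high-fat replicate 3, and male-biased genes -0.31 without wild-type high-fat replicate 1 and -0.31 without knockout high-fat replicate 3. Without knockout high-fat replicate 3, 2 genes passed. The male-biased and MHC class II calls were lost without knockout high-fat replicate 1 (mean -0.04 and 0.08). The call was also lost for insulin signalling without wild-type replicate 3 (-0.15) or knockout replicate 2 (-0.08) or 3 (-0.19) of this diet. It was lost for the unfolded protein response without wild-type 3 (-0.16) or knockout 1 (-0.21) or 2 (-0.15) and for NRF2 genes without wild-type 2 (0.11) or 3 (0.14) or knockout 2 (0.11). For p53 targets it was lost without wild-type 3 (-0.08) or knockout 3 (-0.09) and for pericentral markers without wild-type 1 (0.13) or knockout 1 (0.14) or 3 (0.15). For neutrophil markers it was lost without wild-type 2 (0.29) or knockout 2 (0.28), and for pancreas markers without wild-type 2 (-0.08) or knockout 1 (-0.16).

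**Figure D2:**
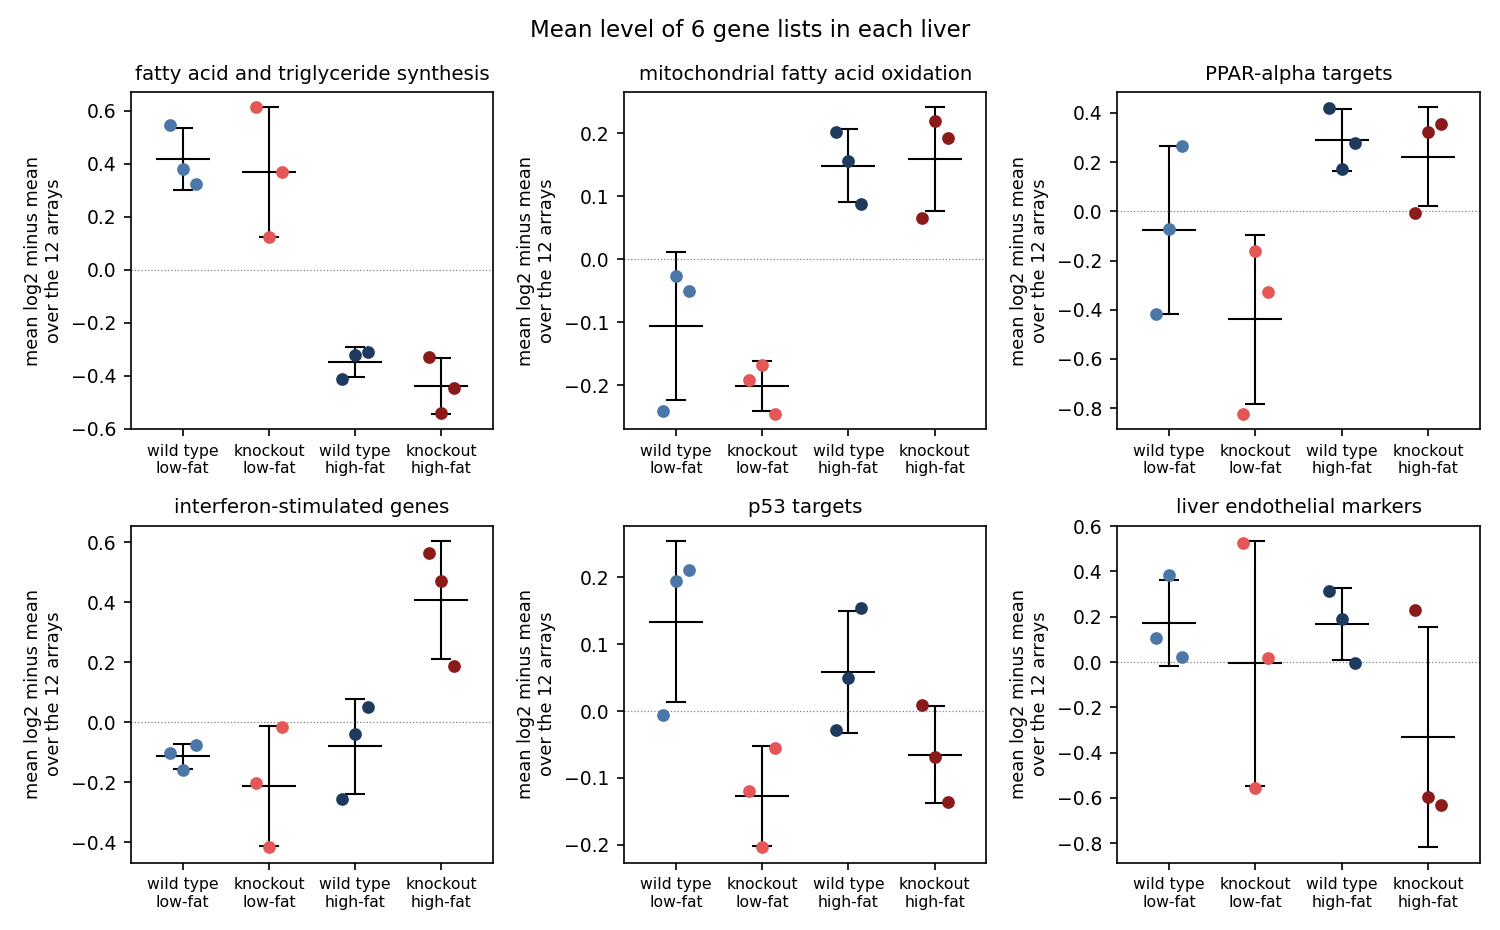
Mean log2 level of 6 gene lists in each liver, minus the mean over the 12 arrays (vertical axes), in the 4 groups (horizontal axis); each point is 1 liver, the long bar is the group mean and the whiskers are ± 1 SD (n = 3). Interferon-stimulated genes stood at 0.19 to 0.56 in the 3 knockout livers on the high-fat diet and at or below 0.05 in the other 9 livers, and fatty acid synthesis was above 0 in all 6 low-fat livers and below 0 in all 6 high-fat livers.

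Averaged over both diets, knockout livers had less Pml and less Ccng1 mRNA than wild-type livers. Ccng1 was 1.42-fold lower (log2 change -0.50, SE 0.0693, limma adjusted p = 0.0428), with -0.51 on the low-fat and -0.50 on the high-fat diet. All 6 knockout livers, at 7.66 to 7.90, lay below all 6 wild-type livers, at 8.15 to 8.42. These values are from its brightest probe set. The dimmer Ccng1 probe sets had -0.52 and -0.61 on the low-fat diet and -0.26 and -0.43 on the high-fat diet. Pml and Ccng1 were the 2 genes past the threshold, with 745 at an unadjusted p under 0.05. Targets of p53 were lower in 13 of 16 members (mean -0.19, camera adjusted p = 0.000244, and adjusted p = 0.454 with an estimated correlation), with Ccng1 past the threshold among all genes and 3 members when adjusted over the list alone. Cdkn1a had -0.99 (SE 0.319, adjusted p = 0.602). PPAR-alpha targets were lower in 11 of 12 members (mean -0.22, camera adjusted p = 0.00557, and adjusted p = 0.517 with an estimated correlation), with 0 past the threshold among all genes and 1 when adjusted over the list alone. Ppara had -0.29 (SE 0.0689, adjusted p = 0.596).

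Higher values on average were found for interferon-stimulated genes (mean 0.20, camera adjusted p = 0.000244, and adjusted p = 0.517 with an estimated correlation). The same held for inflammatory cytokines and chemokines (mean 0.28, median 0.16, camera adjusted p = 0.00418, and adjusted p = 0.517 with an estimated correlation) and the acute phase response (mean 0.08, camera adjusted p = 0.011, and adjusted p = 0.517 with an estimated correlation). On the low-fat diet the interferon and acute phase means were -0.10 and -0.09, so their averages come from the high-fat diet. Liver endothelial markers were lower (mean -0.34, camera adjusted p = 3.6e-05, and adjusted p = 0.642 with an estimated correlation). Among all genes 0 members of these 4 lists passed, against 2 interferon genes and 2 cytokine genes when adjusted over the list alone. Ccng1 passed in 1 of 12 refits that left out an array each (without knockout low-fat replicate 3, adjusted p = 0.0237) and in the other 11 had an adjusted p of up to 0.186 with a log2 change between -0.54 and -0.46. The PPAR-alpha list missed the threshold without wild-type low-fat replicate 3, knockout low-fat replicate 1 or knockout high-fat replicate 1 (mean -0.13, -0.12 and -0.16). The acute phase list missed it without wild-type low-fat replicate 2 (0.01) or knockout low-fat replicate 2 (0.11), and its mean was 0.14 without wild-type low-fat replicate 3 and 0.05 without knockout high-fat replicate 1. The endothelial mean was -0.20 without knockout low-fat replicate 2, and the call was lost without the 2 arrays with the lowest macrophage markers (-0.13), a choice made after seeing the data.

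In wild-type livers the high-fat diet lowered the enzymes that make fatty acids. Scd1, the desaturase that makes monounsaturated fatty acids, fell 6.64-fold (log2 change -2.73, SE 0.178, limma adjusted p = 1.85e-05). This probe set is close to the top of the array's range, where changes tend to be compressed, and the second, dimmer Scd1 probe set had -4.81. The elongase Elovl6 fell 4.27-fold (log2 change -2.10, SE 0.203, adjusted p = 0.000924). Fatty acid synthase, Fasn, fell 3.47-fold (log2 change -1.80, SE 0.268, adjusted p = 0.0176), and the acetyl-CoA carboxylases Acacb and Acaca fell 3.37-fold and 2.45-fold (adjusted p = 0.0176 and 0.011). In the list of fatty acid and triglyceride synthesis 16 of 18 members were lower, 5 of them past the threshold among all genes and 10 when adjusted over the list alone. The mean log2 change was -0.77 and the median -0.47 (camera adjusted p = 6.2e-16, and adjusted p = 0.0533 with an estimated correlation). Of the 18 genes that passed in all, 8 rose and 10 fell, and 905 had an unadjusted p under 0.05.

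Genes of fatty acid breakdown moved the other way. All 18 members of mitochondrial fatty acid oxidation were higher (mean 0.25, camera adjusted p = 5.94e-15, and adjusted p = 0.128 with an estimated correlation). Eci1, an isomerase needed for unsaturated fatty acids, rose 1.59-fold (log2 change 0.67, SE 0.0957, adjusted p = 0.0142). It was the 1 member past the threshold among all genes, against 12 when adjusted over the list alone. Acadm, the medium-chain dehydrogenase, had 0.25 (SE 0.0549, adjusted p = 0.1). Outside the list, Ech1, another enoyl-CoA isomerase, rose 1.70-fold (adjusted p = 0.00402). Peroxisomal fatty acid oxidation was higher in 14 of 15 members (mean 0.12, camera adjusted p = 5.08e-06, and adjusted p = 0.311 with an estimated correlation), with 0 past the threshold among all genes and 6 when adjusted over the list alone. The PPAR-alpha list (mean 0.37, median 0.10) did not pass (camera adjusted p = 0.178), with Cyp4a10 at 1.73 (SE 0.551, adjusted p = 0.338), Fgf21 at 0.56 (SE 0.456) and Ppara at -0.07 (SE 0.0975).

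Fitm1, a lipid droplet protein, rose 2.32-fold (adjusted p = 0.0274). The other genes that rose were Cox6b2, a subunit of cytochrome c oxidase (2.50-fold, adjusted p = 0.00125), Meg3, a long non-coding RNA (3.28-fold), Treh (2.22-fold), Nt5e (1.93-fold) and Them7 (1.62-fold). Those that fell included Reck (2.39-fold), Rnd2 (2.32-fold), Kcnh3 (1.92-fold) and the growth factor Vegfb (1.89-fold). Cholesterol synthesis and uptake was lower in 15 of 17 members (mean -0.44, camera adjusted p = 4.63e-07, and adjusted p = 0.43 with an estimated correlation), with Fdps at -1.37, 0 members past the threshold among all genes and 5 when adjusted over the list alone. Periportal hepatocyte markers were lower in 10 of 10 members (mean -0.32, median -0.19, camera adjusted p = 4.15e-06, and adjusted p = 0.177 with an estimated correlation), with 0 among all genes and 6 adjusted over the list alone. Pericentral markers were higher in 10 of 11 (mean 0.21, camera adjusted p = 0.00996, and adjusted p = 0.43 with an estimated correlation), with 0 and 0. Targets of the constitutive androstane and pregnane X receptors were lower (mean -0.14, camera adjusted p = 0.0437, and adjusted p = 0.497 with an estimated correlation), with 0 and 3. Exocrine pancreas markers were higher (mean 0.20, camera adjusted p = 0.0472, and adjusted p = 0.409 with an estimated correlation), with 0 and 0.

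The number of genes past the threshold depended on single arrays, with 6 without wild-type low-fat replicate 1, 11, 5 and 9 without wild-type high-fat replicates 1, 2 and 3, and 39 and 28 without knockout low-fat replicates 2 and 3. Of the 18 genes 4 passed in each of the 12 refits, Scd1, Elovl6, Cox6b2 and Ech1. Fasn missed the threshold in 5 of them, Acacb in 4, Acaca in 3 and Eci1 in 3. The mean of peroxisomal fatty acid oxidation was 0.03 without wild-type low-fat replicate 1 and 0.06 without wild-type high-fat replicate 1, and that of cholesterol synthesis and uptake was -0.29 without wild-type low-fat replicate 1, with the calls kept. The receptor and pancreas lists both missed the threshold without wild-type high-fat replicate 2 (mean -0.07 and 0.10) or knockout low-fat replicate 2 (-0.14 and 0.20). The receptor list also missed it without wild-type low-fat replicate 3 (-0.09), wild-type high-fat replicate 3 (-0.14) or knockout low-fat replicate 3 (-0.14), and the pancreas list without wild-type low-fat replicate 1 (0.20) or 2 (0.19) or knockout high-fat replicate 2 (0.20). With other scaling, quantile normalization gave 34 genes, 15 higher and 19 lower, and median centring 39, 15 higher and 24 lower.

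In knockout livers the same comparison of diets gave 311 genes past the threshold, 180 higher and 131 lower on the high-fat diet, with 1881 at an unadjusted p under 0.05. The lipogenic enzymes fell here too, with Scd1 down 4.97-fold (log2 change -2.31, SE 0.178, limma adjusted p = 0.00013), and by -4.18 on the log2 scale at its second probe set. The others fell as well: Fasn 3.80-fold, Acacb 3.31-fold, Me1, which supplies NADPH for fatty acid synthesis, 3.26-fold, Acaca 3.26-fold and Elovl6 3.14-fold. Of 18 members of fatty acid and triglyceride synthesis 15 were lower, 7 past the threshold among all genes and 10 when adjusted over the list alone (mean -0.81, median -0.54, camera adjusted p = 6.15e-09, and adjusted p = 0.159 with an estimated correlation). All 18 genes of mitochondrial fatty acid oxidation were higher, 7 past the threshold among all genes and 15 when adjusted over the list alone (mean 0.36, camera adjusted p = 6.75e-13, and adjusted p = 0.159 with an estimated correlation). Among them Eci1 rose 1.66-fold, Etfdh 1.44-fold, the carnitine carrier Slc25a20 1.39-fold and Acadm 1.30-fold (SE 0.0549 on the log2 scale, adjusted p = 0.00448). Cpt1a had a log2 change of 0.36 (SE 0.0995, adjusted p = 0.0702).

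Peroxisomal fatty acid oxidation was higher in 14 of 15 members, 4 past the threshold among all genes and 10 when adjusted over the list alone (mean 0.35, camera adjusted p = 2.79e-08, and adjusted p = 0.159 with an estimated correlation). Decr2 was up 1.67-fold and Ehhadh, the peroxisomal bifunctional enzyme, 1.52-fold. PPAR-alpha targets were higher in 10 of 12 members, 2 past the threshold among all genes and 3 when adjusted over the list alone (mean 0.66, median 0.26, camera adjusted p = 0.0107, and adjusted p = 0.478 with an estimated correlation). Those 2 were Vnn1, a pantetheinase, up 7.34-fold (log2 change 2.88, SE 0.686, adjusted p = 0.0436), and Cyp4a10, up 5.75-fold (log2 change 2.52, SE 0.551, adjusted p = 0.0305). Ppara had 0.30 (SE 0.0975, adjusted p = 0.12), Angptl4 -0.16 (SE 0.233), and Fgf21 0.69 (SE 0.456). The fatty acid transporter Cd36 had 1.01 (SE 0.304, adjusted p = 0.0937) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 0.89 (SE 0.411). Fitm1 rose 3.35-fold and Fabp2, a fatty acid binding protein, 1.54-fold.

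Interferon-stimulated genes were higher in 20 of 21 members, 6 past the threshold among all genes and 15 when adjusted over the list alone (mean 0.62, camera adjusted p = 3.98e-11, and adjusted p = 0.159 with an estimated correlation). Ifit1 rose 2.69-fold, Ifit3 2.59-fold (SE 0.167 on the log2 scale, adjusted p = 0.00225), the interferon-induced GTPase Igtp 2.10-fold and Xaf1 2.04-fold. Acute phase genes had 3 members past the threshold among all genes and 6 when adjusted over the list alone (mean 0.50, median 0.17, camera adjusted p = 0.0031, and adjusted p = 0.174 with an estimated correlation). The iron-binding Lcn2 rose 7.35-fold (log2 change 2.88, SE 0.417, adjusted p = 0.00435), Saa2 3.33-fold and Saa1 3.14-fold. The knockout high-fat livers in this comparison are those that were set against wild-type livers above, and their endothelial markers lay between -0.63 and 0.23.

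Pericentral hepatocyte markers were higher in 10 of 11 members (mean 0.36, camera adjusted p = 0.000437, and adjusted p = 0.185 with an estimated correlation). Oat, which rose 1.54-fold, was the 1 member past the threshold among all genes, against 5 when adjusted over the list alone. Periportal markers were lower in 10 of 10 (mean -0.49, median -0.16, camera adjusted p = 0.000437, and adjusted p = 0.185 with an estimated correlation), with 3 past the threshold among all genes and 4 adjusted over the list alone. Etnppl fell 5.34-fold, Cdh1 2.23-fold and the histidine-degrading Hal 1.41-fold. PML nuclear body components were lower in 9 of 11 members (mean -0.20, camera adjusted p = 0.022, and adjusted p = 0.311 with an estimated correlation). Rb1, down 1.49-fold, and Hipk2, down 1.37-fold, were the 2 past the threshold among all genes, against 2 when adjusted over the list alone. Further genes that rose were Rad51b (4.64-fold), Meg3 (3.69-fold), Pdzrn3 (3.36-fold), Cyp2c37 (1.88-fold), the bile acid enzyme Akr1d1 (1.69-fold), Aldh1a1 (1.47-fold) and Acat1 (1.44-fold). Atg16l2 fell 2.78-fold, Vegfb 2.72-fold, Reck 2.46-fold, the hepatocyte transcription factor Hnf4a 1.31-fold, the glycogen synthase Gys2 1.29-fold, the bile salt export pump Abcb11 1.29-fold and Apoa5 1.22-fold.

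The count of 311 fell to 111 and 151 without knockout low-fat replicates 1 and 2 and to 188, 71 and 136 without knockout high-fat replicates 1, 2 and 3. It was 69 without the 2 arrays with the lowest macrophage markers, chosen after seeing the data, and 68 in a fit of the knockout arrays alone. Of 54 named genes past the threshold 24 passed in each of the 12 refits, and 30 lost the call without knockout high-fat replicate 2, 26 without knockout low-fat replicate 2 and 22 without knockout low-fat replicate 1. Vnn1 missed it in 9 of 12 refits (log2 change 2.10 without knockout low-fat replicate 1 and 2.52 without knockout high-fat replicate 2). Cyp4a10 missed it in 5, without knockout low-fat replicate 1 (1.81) or 2 (2.72) or knockout high-fat replicate 1 (2.62), 2 (2.41) or 3 (2.53). Ifit1 missed it in 7, Xaf1 in 9, Slc25a20 in 10, Ehhadh in 4, Fabp2 in 8, Rb1 in 9, Hal in 10, Saa1 in 3 and Saa2 in 3. The PPAR-alpha list missed the threshold without knockout low-fat replicate 1 (mean 0.47) or 3 (0.72) or knockout high-fat replicate 2 (0.61), the PML list without knockout low-fat replicate 3 (-0.15). Median centring moved the split of called genes to 284 higher and 115 lower.

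The diet responses of the genotypes were then set against each other. All 18 genes that passed in wild-type livers also passed in knockout livers and in the same direction, where 0.546 would be shared by independent lists of these sizes. The 2 lists are not independent, since both comparisons use the same variance estimate of each gene. Of the 293 genes that passed in knockout livers alone, 268 had the same direction in wild-type livers. The genes raised in knockout livers had a median log2 change of 0.62 there and 0.27 in wild-type livers, and the lowered genes -0.53 and -0.21. Genes picked in knockout livers are picked partly for chance values there. Across all genes tested, which are not independent replicates, Pearson's r between the changes of diet in the 2 genotypes was 0.461 (Spearman's rho 0.377), and that between the changes of genotype on the 2 diets was 0.0643 (rho 0.0622). Different arrays entered the 2 sides of each of these correlations.

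**Figure D3:**
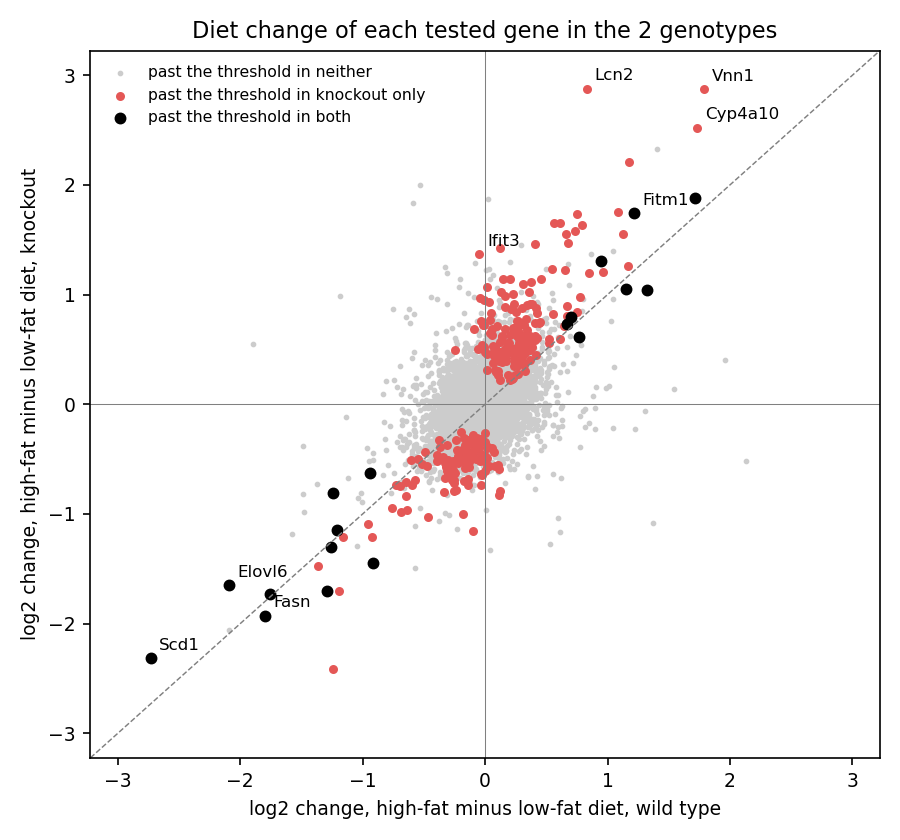
Log2 change from the low-fat to the high-fat diet in wild-type livers (horizontal axis) and in knockout livers (vertical axis); each point is 1 of the 10258 genes tested, black points passed in both genotypes, red points in knockout livers, and the dashed line marks equal changes. Scd1 lay near the dashed line at -2.73 and -2.31, and Ifit3 was at -0.05 in wild-type and 1.37 in knockout livers.

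The difference between the 2 diet responses passed for no single gene (0 of 10258 in limma, 585 at an unadjusted p under 0.05), and for 1 gene without knockout low-fat replicate 3. The 5 genes with the smallest p, none past the threshold, were Ifit3 (log2 difference 1.42, SE 0.236, adjusted p = 0.366), Srpk1 (-0.94), Mterf2 (1.06), Zfp771 (-0.61) and Slc35e3 (-0.63). The response of Ppara differed by 0.36 (SE 0.138, adjusted p = 0.827), that of Cyp4a10 by 0.79, and that of Scd1 by 0.42. Among the 4 lists that passed, interferon-stimulated genes had the largest mean difference, while female-biased liver genes, at 0.59, did not pass (camera adjusted p = 0.0529). The response was higher in knockout livers for 21 of 21 members (mean 0.59, camera adjusted p = 7.06e-11, and adjusted p = 0.489 with an estimated correlation), with 0 past the threshold among all genes and 2 when adjusted over the list alone. The list mean was -0.11 ± 0.0423 (SD, n = 3) and -0.08 ± 0.157 in wild-type livers on the low-fat and high-fat diets and -0.21 ± 0.201 and 0.41 ± 0.197 in knockout livers.

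Targets of the constitutive androstane and pregnane X receptors (mean 0.23, camera adjusted p = 0.000529, and adjusted p = 0.489 with an estimated correlation) and acute phase genes (mean 0.33, median 0.07, camera adjusted p = 0.0478, and adjusted p = 0.489 with an estimated correlation) also responded more upwards in knockout livers. Male-biased liver genes responded more downwards (mean -0.25, camera adjusted p = 0.0478, and adjusted p = 0.714 with an estimated correlation). There were 0 members of these 3 lists past the threshold among all genes and 0 adjusted over the list alone. Lcn2 had the largest value among the acute phase genes, 2.05 (SE 0.59). The PPAR-alpha list (mean 0.30) and mitochondrial fatty acid oxidation (mean 0.11) did not pass (camera adjusted p = 0.127 for both). The acute phase call was lost without wild-type low-fat replicate 3 (0.22), wild-type high-fat replicate 1 (0.33) or 3 (0.33), knockout low-fat replicate 3 (0.37) or knockout high-fat replicate 2 (0.35). The male-biased call was lost without knockout high-fat replicate 1 (-0.10), wild-type high-fat replicate 2 or 3 (-0.21 and -0.19), wild-type low-fat replicate 3 (-0.20) or knockout low-fat replicate 2 or 3 (-0.19 and -0.26).

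Across the 6 comparisons none of the 45 list calls held with an estimated correlation between genes. By fry, which asks whether a list's genes moved one way on balance, 2 lists passed for diet in wild-type livers, fatty acid and triglyceride synthesis (adjusted p = 0.00313) and mitochondrial fatty acid oxidation (adjusted p = 0.0368), and 10 passed for diet in knockout livers. There were 0 in each of the other comparisons, where 3, 15, 6 and 4 had passed camera. Random splits of the same arrays also gave many list calls with the preset correlation, as many as 16 of 38 lists. A list call here stands for the size and direction of its members' values and not for a test that holds across settings.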

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

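The macrophage test of the interferon pattern was chosen only after the result was seen. So was the use of the planned refits without each array as a test of this pattern. A difference between the genotypes' diet responses, tested as an interaction, brought up 4 gene lists: interferon-stimulated genes (mean log2 difference 0.587, higher in 21 of 21 members), targets of the constitutive androstane and pregnane X receptors (0.229, 12 of 14 higher), male-biased liver genes (-0.254, 12 of 13 lower) and acute phase genes (0.333, median 0.071, 17 of 24 higher). All passed camera at the preset correlation, and none with an estimated correlation (adjusted p = 0.489, 0.489, 0.714 and 0.489). Of 100 splits of genotype within each diet 80 called as many lists as the real 4, with up to 14 in another split, so chance cannot be excluded for the number of lists. For single genes 100 of 100 splits reached the real count of 0, and 9 called more. Up to 25 passed in another split, and whether this reflects structure among the livers was not tested. In that split the macrophage level changed with diet by -0.107 on one side and 0.650 on the other, and whether this accounts for the count was not tested.

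Probe sets that carry no gene name here take no part in the comparisons above, and 9353 of them were tested in the same way. In wild-type livers 1 passed for diet (0 higher, 1 lower), in knockout livers 11 passed (6 higher, 5 lower), and 1 passed for the difference between the diet responses (1 higher, 0 lower). By limma 783, 896 and 520 had an unadjusted p under 0.05. For genotype on the low-fat diet, on the high-fat diet and averaged, 0 passed, with 702, 406 and 573 at an unadjusted p under 0.05.

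Interferon-stimulated genes were higher in knockout than in wild-type livers on the high-fat diet, by a mean log2 change of 0.488. The call held in neither alternative (adjusted p = 0.147 with an estimated correlation and 0.128 by fry). Of 100 splits 3, the real one included, gave a difference in diet response as large as 0.587 (up to 0.646 in another split). Chance is thus excluded at a share of 0.05 for the difference in diet response of this list taken alone, though not for the choice of the list among 38. It is not excluded for the difference on the high-fat diet itself, since the splits of the high-fat livers alone are too few. A single array as the whole source is argued against by the lowest leave-one-out value of the list, 0.401 (highest adjusted p = 3.97e-07 at the preset correlation), and more macrophages as the whole source by a shift of 0.508 with the macrophage level as a term (adjusted p = 4.92e-17 at the preset correlation). None of the 15 tested macrophage markers is in another list. Their mean level on this diet was 6.585, 6.764 and 6.557 in the wild-type livers and 7.059, 6.722 and 5.853 in the knockout livers. These levels overlapped, so the term for them had no steady excess to remove. Most of the 15 markers had a lower mean in knockout than in wild-type livers on this diet. The 3 with the brightest signal in wild-type livers, Cd5l, Mpeg1 and Vsig4, went both ways, with 8.30, 8.27 and 7.56 there and 8.53, 8.69 and 6.98 in knockout livers. Other immune cells stay open, since 4 T and NK cell and 2 B and plasma cell markers were too few for a list test. Neutrophil markers were tested and were higher in knockout livers on this diet (mean 0.301, camera adjusted p = 0.0287 at the preset correlation). That call was lost with an estimated correlation, by fry and without some single arrays, and whether neutrophils account for the interferon pattern was not tested. An infection of some livers also stays open and was not tested. A stronger interferon response to the diet without Pml may be an untested biological hypothesis.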

How the results depend on the processing

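The fit without the 2 arrays with the lowest macrophage markers and the PML list without Pml were chosen only after the result was seen. Of 3944 values of 175 named-gene results under the alternatives, 3522 kept their side of the threshold, 413 no longer passed and 9 newly passed. A reversal of direction was counted only where the gene passed under the main setting or the alternative, and 0 were found. Of 1077 values of the 45 list calls, 899 kept their direction and side of the threshold, 178 no longer passed and 0 reversed. Unless said otherwise the cause was not tested.

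With an estimated correlation 0 lists passed in each of the 6 comparisons by camera. By fry 0 passed for genotype on the low-fat diet, on the high-fat diet, averaged and for the interaction, and 2 for diet in wild-type livers. At an adjusted p of 0.10, 65 genes passed for diet in wild-type and 655 in knockout livers. For diet in wild-type livers 34 genes passed with quantile normalization, 39 with median centring and 109 with array weights. For the interaction 2 lists passed with quantile normalization, 2 with median centring, 2 without the variance trend, 9 without the filter and 9 with the replicate block. For genotype averaged over diets 1 gene passed without the filter, 1 without the trend and 1 with the block. In each of these settings it was Pml, so Ccng1 no longer passed. With the stricter filter 0 genes passed for genotype on the low-fat diet, 0 on the high-fat diet and 0 averaged, and with the mean of probe sets 0 on the high-fat diet and 0 averaged. In both settings Pml fell under the filter and gave no value, and the 1 gene that passed on the low-fat diet with the mean of probe sets was another gene. Ccng1 stayed over the filter in both settings but did not pass for the average. For genotype on the low-fat diet 0 genes passed with the block and 0 with array weights. With the 2 groups alone 0 passed for genotype on the high-fat diet and 68 for diet in knockout livers, where fewer arrays give the spread. Without the 2 arrays with the lowest macrophage markers 0 genes and 5 lists passed for genotype on the low-fat diet, 3 genes on the high-fat diet, 5 genes averaged, 69 genes for diet in knockout livers and 11 lists for the interaction. The PML list without Pml had an adjusted p = 0.0247 for genotype on the high-fat diet and 0.0259 for diet in knockout livers. Neither call held, with adjusted p = 0.317 and 0.251 with an estimated correlation.

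Leaving out 1 array at a time gave, for genotype on the low-fat diet, 0 to 4 genes (4 without knockout low-fat replicate 1) and 0 to 7 lists, and on the high-fat diet 1 to 2 genes and 11 to 15 lists. For diet it gave 5 to 39 genes and 6 to 11 lists in wild-type livers and 71 to 461 genes and 7 to 15 lists in knockout livers. Averaged over diets it gave 1 to 2 genes and 6 to 10 lists, for the interaction 0 to 1 genes and 2 to 13 lists, and for Pml a log2 change of -1.753 to -1.559. For the called genes of diet in knockout livers 300 of 311 were shared with the 420 of quantile normalization (256 higher, 164 lower) and 270 with the 399 of median centring (284 higher, 115 lower).

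Deviations from the group means of extracts with the same number had r from -0.166 to 0.381, with 7 of 18 pairs over 0.1. For 6 of 12 arrays the closest array of another group by these deviations had the same number. These values do not settle whether the numbers are pairs, and the numbers were left out of the main fit because the labels do not say so. With them as a block 22 genes passed for diet in wild-type and 310 in knockout livers. The 40% of genes with the lowest mean were left out by choice, so they were tested in full in the alternative without the filter alone, and signal over background itself was not measured here.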

Other observations

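Leaving out each array was planned, but its use as a test of the diet counts was chosen only after the result was seen. The tests of the DNA flanking Pml and of the p53 genes within it were also chosen only after the result was seen. More genes passed for diet in knockout (311) than in wild-type livers (18), a difference of 293. Of 100 splits of genotype within each diet 2, the real one included, gave a difference as large, the other being 423. Chance is thus excluded at a share of 0.05 for this difference taken alone, though not for its choice among the patterns looked at. Whether the split with 423 reflects structure among the livers was not tested. The macrophage marker levels of its sides were 6.64 and 6.27, and whether these account for the count was not tested either. A single array as the whole source is argued against by the smallest difference without 1 array, 53 (71 against 18, without knockout high-fat replicate 2). This is far below 293, so the size of the difference depended on that array. In fits of each genotype alone the counts were 68 and 20, and the interaction passed for 0 genes by limma (585 at an unadjusted p under 0.05), so the counts may differ more than the responses do. A stronger diet response without Pml stays open as an untested hypothesis.

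Ccng1 and the mean of p53 targets were lower in knockout livers on both diets. On the high-fat diet the list mean was -0.124, and that call was lost without wild-type high-fat replicate 3 or knockout high-fat replicate 3. For the average over both diets 1 of 100 splits, the real one, gave a mean shift of the list as large as 0.192 (0.179 in the next). Chance is thus excluded at a share of 0.05 for this list and this average taken alone, though not for their choice among 38 lists and 6 comparisons. The list call for the average had a camera adjusted p = 0.454 with an estimated correlation. A strain variant under 1 Ccng1 probe set as the whole source is argued against by the next brightest probe set, with an average of -0.388 against -0.501. That probe set had -0.516 on the low-fat and -0.26 on the high-fat diet. Genes of the p53 list within the DNA flanking Pml number 0 of 16, with neighbours taken from GRCm38.p6, 200 to each side. DNA of another strain around Pml cannot be told apart from its loss: of 110 flanking genes tested 10% had a p under 0.05 against 7.22% of the others (1-sided Fisher p = 0.173, odds ratio 1.43, 95% interval 0.687 to 2.68), and the background strain is not given in the sources used here. Weaker p53 activity without Pml, which binds p53 in nuclear bodies, may be a hypothesis that these data leave untested.

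Splits of the 6 livers of a comparison number 10, too few for a share under 0.05. For genotype on the low-fat diet 2 of 10 splits called as many genes as the real 1 (up to 1 in another split) and 9 as many lists as the real 3 (up to 13). On the high-fat diet the numbers were 1 split for genes (real 1, up to 0 in another) and 1 for lists (real 15, up to 11). For diet in wild-type livers they were 1 for genes (real 18, up to 0) and 4 for lists (real 8, up to 12), and in knockout livers 1 for genes (real 311, up to 9) and 6 for lists (real 9, up to 16). For genotype averaged over diets 4 of 100 splits called as many genes as the real 2. One of these is Pml, the gene that was knocked out, and the other, Ccng1, passed in 1 of 12 refits without an array, so the share says little about other genes. Of the 4 splits 2 called more, with up to 25 in a split with mean macrophage levels of 6.64 and 6.27. Whether this reflects structure among the livers was not tested. For lists 58 of 100 called as many lists as the real 6 (up to 15), so chance cannot be excluded for these.

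The probe sets of a gene did not always give the same size of change. For Scd1 in wild-type livers the brightest probe set had a log2 change for diet of -2.73 and a second had -4.81, and in knockout livers they had -2.31 and -4.18. For Ppara in the comparison of genotypes on the low-fat diet 3 probe sets had -0.47, -0.80 and -0.45, and for Cd36 in knockout livers 3 had 1.01, 1.41 and 0.53 for diet. Among genes under the filter Cyp2b10 had -1.29 for genotype on the high-fat diet (SE 0.372) and Pparg had 0.52 for diet in wild-type livers (SE 0.188), neither past the threshold in a fit without a filter (adjusted p = 0.978 and 0.503).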
